A study of Homo sapiens with 50 samples.

How the data were processed

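RNA from HEK293T cells was sequenced in 50 libraries of 25 groups, 2 libraries each. Per the labels, total RNA was made into libraries with a stranded mRNA kit. Reads were trimmed with cutadapt 1.4.0, aligned to hg19 with STAR 2.4.0i and assigned to genes with featureCounts 1.5.0, and DESeq2 1.10.1 was listed as well, all per the submitters' processing notes. The values were deposited as RPKM in 4 tables, per the submitters' processing notes. No other step between reads and RPKM is stated there. The tables listed 19316, 17508, 24060 and 24792 genes, every column was used, and no 2 libraries were identical. Gene identifiers were given symbols from the reference annotation for 96.5, 97.2, 95.6 and 95.5 percent of genes. The labels also describe polysome samples, which are not analysed here.

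Reads were recovered from the RPKM values and counted as whole within a tolerance of 0.01. With the annotated gene length this held for 64.4, 64.3, 66.8 and 66.6 percent of genes in the 4 tables, and with that length or the step between the gene's own values for 95.3, 96.6, 98.2 and 94.8 percent. The depth computed in this way was 30.8 to 39.7 M reads per library in the first table, 24.3 to 63.6 in the second, 14.4 to 45.4 in the third and 31.6 to 47.9 in the fourth. The control of the second table was skewed by gene GC content against the other controls, and all tests were therefore made within a table.

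Genes with RPKM of at least 1 in at least 2 libraries of a table were tested, which left 15716, 11993, 15697 and 16118. RPKM was rescaled by median-ratio factors, and log2(RPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with a mean for each group, an intensity trend and robust moderation, on all libraries of the table. The hairpins of a target were averaged with equal weight. Adjusted p-values are Benjamini-Hochberg over all tested genes of a comparison, and under 0.05 counts as past the test. A total of 14 comparisons with a control and the difference between TOB1 and TOB2 were tested, and the hairpins of 7 targets were compared with each other. Gene lists, 35 in number and fixed with the comparisons before the data were examined, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, where at least 5 members were measured. These list p-values were adjusted over the lists of a comparison. Members were also counted with p adjusted over the list alone. All moderated t and camera tests rest on 2 libraries per group, and no exact test can reach significance at that size.

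Genes are named by a fixed rule. It takes the targeted gene, then the 7 highest and 7 lowest log2 changes among genes past the test with a mean RPKM of at least 1 and every treated library on the same side of both controls. It adds the 3 members with the smallest p in the direction of the list for the 4 lists with the smallest camera p. Names of clones and of pseudogenes beside a tested parent were passed over. Where no gene qualified, the 3 smallest p-values are named as not past the test, and for TOB1 against TOB2 only 5 genes each way are named.

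The alternatives set with the design were pseudocounts of 0.1 and 1, no expression filter, RPKM as deposited, the replicate number as a block, the compared groups alone in the fit, each hairpin alone, each library left out in turn, and the estimated correlation. Others were chosen after seeing the data. These were an adjustment for GC content and gene length by natural splines with 5 degrees of freedom each, voom on the recovered reads, lists without the targeted gene, and fits without CNOT7-sh2 replicate 1 or MTDH-sh1 replicate 1. GC content was known for 15284, 11707, 15234 and 15606 of the tested genes.

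The procedure was tested on simulated data with 200 changed genes, 100 at each of 2 sizes. It recovered 58 percent of 1.5-fold and 90 percent of 2-fold changes in the design of UBAP2L, 75 and 97 percent in that of DDX6, 79 and 94 percent in that of TOB1, and 2 and 57 percent in that of PARN. Overlaps of comparisons with a shared control were set against 20 simulated draws of unchanged groups. Every library, controls included, was redrawn with independent errors per gene, so a shift of a whole library was not simulated. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.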

Results

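Gene expression was profiled by RNA sequencing in HEK293T cells, a human embryonic kidney line, after knockdown of 8 genes or overexpression of 6 others. The series title places these factors in a study of tethered function assays, in which a protein is brought to a reporter mRNA to read its effect on stability and translation. The targets were RNA-binding proteins, deadenylases and other regulators of mRNA. The 50 libraries formed 25 groups of 2 and came in 4 separately normalised tables. The first table (12 libraries) held Control-1 with knockdowns of CLK3, CNOT7 and UBAP2L, the second (14) Control-2 with AIMP1, DDX6 and MEX3C, the third (10) Control-3 with MTDH and PARN, and the fourth (14) a FLAG control with overexpressed BOLL, IFIT2, NANOS3, SNRPA, TOB1 and TOB2. Each knockdown used 2 hairpins except that of CLK3, which had 1. Depth, recovered from the steps between low values, was 14.4 to 63.6 M reads per library. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Log2 changes and folds are on the log2(RPKM + 0.5) scale and understate the change of low genes. Libraries came from an mRNA kit, so for noncoding RNAs and histone mRNAs a change in amount was not told apart from a change in capture. Levels are means ± SD in RPKM with n = 2 libraries per group, the hairpins are given in the order 1 and 2, and errors of log2 changes are SE.

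The targeted genes were examined first. All 8 knockdown targets were lower in every targeted library than in both controls, and all 6 overexpressed genes were higher. CNOT7, a deadenylase of the CCR4-NOT complex, fell from 14.6 ± 0.037 RPKM to 1.31 ± 0.016 and 1.65 ± 0.41 with hairpins 1 and 2, a log2 change of -2.93 ± 0.1 (limma adjusted p = 3.81e-06). CLK3 fell from 6.48 ± 0.039 to 2.19 ± 0.00034 RPKM (log2 change -1.36 ± 0.09, limma adjusted p = 0.000363), and UBAP2L from 25.4 ± 1.3 to 11.5 ± 0.078 and 8.02 ± 0.57 RPKM (log2 change -1.36 ± 0.07, limma adjusted p = 0.000231). AIMP1 was listed at 0.723 ± 0.23 RPKM in Control-2 against 0.139 ± 0.0049 and 0.199 ± 0.023. DDX6 was listed at 0.435 ± 0.0064 against 0.0897 ± 0.017 and 0.0535 ± 0.015, and MEX3C at 0.292 ± 0.021 against 0.0668 ± 0.032 and 0.0525 ± 0.027. Some libraries without the hairpin also lay below both controls. DDX6 stood at 0.163 to 0.221 in the MEX3C libraries, MEX3C at 0.199 to 0.261 in the DDX6 libraries. AIMP1 stood at 0.225 and 0.347 with MEX3C hairpin 2 and at 0.54 to 1.01 in the other MEX3C and the DDX6 libraries. In the AIMP1 libraries DDX6 (0.512 to 1.02) and MEX3C (0.346 to 0.524) lay above both controls. The targeted libraries were lowest for each gene. These 3 genes lay under the expression filter and were tested in the fit without it, where each fell (log2 changes -0.81 ± 0.12, -0.68 ± 0.12 and -0.46 ± 0.07, limma adjusted p = 0.000285, 0.00292 and 0.000193). At such low levels the size depends on the pseudocount. With 0.1 the log2 changes were -1.53, -1.6 and -1.19, and with 1 they were -0.52, -0.4 and -0.26, all past the test. After the adjustment for GC content and gene length MEX3C stood at -0.23 (limma adjusted p = 0.00671). PARN fell from 7.44 ± 0.41 RPKM to 3.46 ± 0.24 and 0.994 ± 0.23 (log2 change -1.67 ± 0.13, limma adjusted p = 0.0189). MTDH stood at 21 ± 0.37 RPKM in Control-3 and at 7.24 ± 2.9 and 6.24 ± 0.24 in its knockdown, below both controls in 4 of 4 libraries, without passing the test (log2 change -1.54 ± 0.21, limma adjusted p = 0.281). Without MTDH-sh1 replicate 1 or 2 it passed (limma adjusted p = 0.000155 and 0.000131). Among the overexpressed genes, SNRPA rose from 69.6 ± 0.43 to 5540 ± 21 RPKM, TOB1 from 9.04 ± 0.022 to 10405 ± 371, and TOB2 from 13.4 ± 0.47 to 7140 ± 298. BOLL rose from 9.01 ± 1 to 6803 ± 46, NANOS3 from 0.409 ± 0.00059 to 17024 ± 1420 and IFIT2 from 0.0798 ± 0.013 to 6317 ± 299. The largest limma adjusted p of these 6 was 8.71e-13, for BOLL. BOLL, a germ cell gene, was listed at 9.74 and 8.27 RPKM in the FLAG libraries and at 0 to 0.135 in the groups that overexpressed another gene. Its fall was thus common to those 5 groups, and the source of the reads in the FLAG libraries was not tested.

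**Figure D1:**
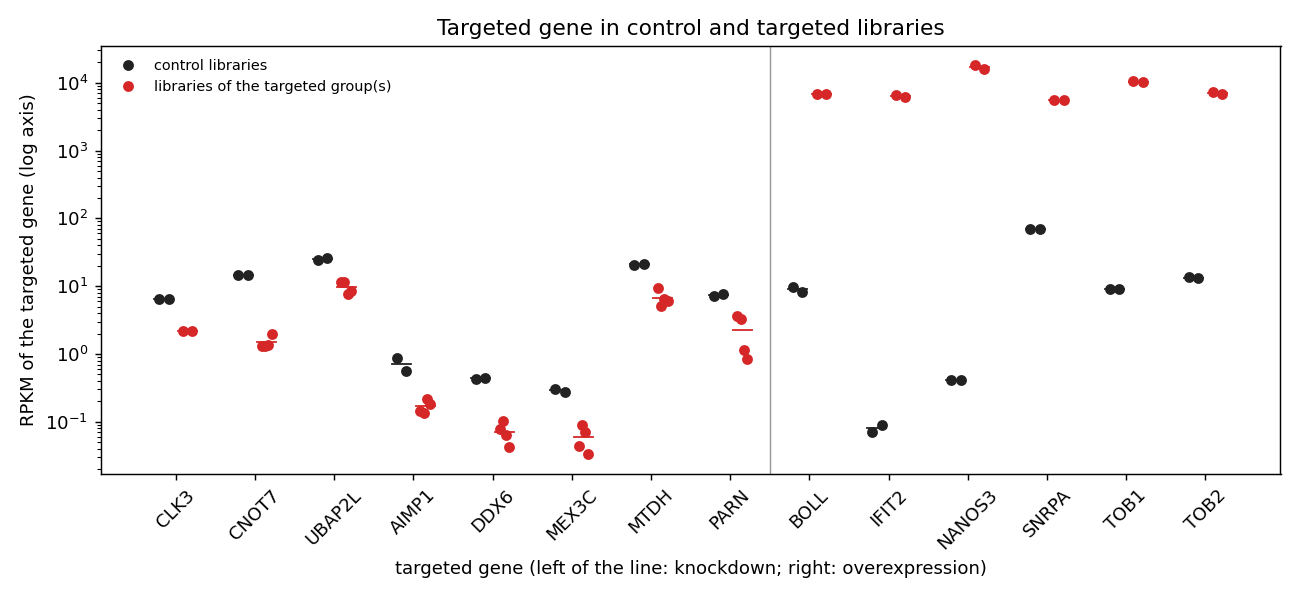
RPKM of each targeted gene (log axis) in the control libraries (black points) and in the libraries of its targeted groups (red points), with short lines at the means. All targeted libraries lie below both controls for the 8 knockdowns and above both for the 6 overexpressions.

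Knockdown of CLK3, a kinase that phosphorylates SR splicing factors, was compared with Control-1 to ask which transcripts depend on it. IDH1, the cytosolic isocitrate dehydrogenase, fell from 8.96 ± 0.59 to 2.43 ± 0.073 RPKM (log2 change -1.68 ± 0.08, limma adjusted p = 0.000101). HMGA2, an architectural chromatin protein, fell from 5.27 ± 0.29 to 1.24 ± 0.22 RPKM (log2 change -1.72 ± 0.16, limma adjusted p = 0.00142). CNOT6, a deadenylase subunit of the CCR4-NOT complex, fell 2.69-fold from 14.9 ± 0.44 RPKM, and the ubiquitin ligase RNF167 2.75-fold from 35.9 ± 1 RPKM. POC1B fell 3.03-fold, ACBD5 2.96-fold and SNN 2.54-fold. SLC2A3, a glucose transporter, rose from 4.61 ± 0.28 to 13.1 ± 2.7 RPKM (log2 change 1.41 ± 0.14, limma adjusted p = 0.0015), together with its near-identical copy SLC2A14, with which it can share reads. CGA, the common subunit of the glycoprotein hormones, rose 2.87-fold from 0.917 ± 0.21 RPKM and PCK1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, 1.82-fold from 2.08 ± 0.048 RPKM. In total 197 genes rose and 371 fell of 15716 tested. The list of G1/S and E2F targets (39 measured) was higher, with a median log2 change of 0.15 (camera adjusted p = 0.00131, and adjusted p = 0.581 with an estimated correlation). Of its members 1 rose and 2 fell, or 4 and 3 adjusted over the list alone. The origin recognition gene ORC1 stood at 19.9 ± 0.9 RPKM in Control-1 and 27.2 ± 1.6 in the knockdown (log2 change 0.45 ± 0.09, limma adjusted p = 0.0283). TGF-beta and SMAD targets (18 measured) were lower (camera adjusted p = 0.0266, and adjusted p = 0.581 with an estimated correlation), none rising and 2 falling, or 5 falling adjusted over the list alone. Those were the basement membrane collagen COL4A1, from 6.88 ± 0.27 to 3.61 ± 0.076 RPKM, and NOG, a secreted BMP antagonist, from 2.95 ± 0.2 to 1.62 ± 0.05 RPKM. The SR proteins and their CLK kinases, the substrates and relatives of CLK3, did not pass the list test (camera adjusted p = 0.843, and 0.456 without CLK3 itself). The count of changed genes was 61 without control ctrl-2, 80 without ctrl-3, 67 and 157 without CLK3-sh1 replicate 1 or 2. It was 3585 without CNOT7-sh2 replicate 1 and 2053 with the compared groups alone in the fit. Leaving out 1 library ended the calls of ACBD5, ORC1, NOG and PCK1 in at least 1 fit (highest limma adjusted p = 0.0564, 0.233, 0.225 and 0.0804) and that of the TGF-beta list in 2 of 5 fits (highest camera adjusted p = 0.102). That list did not pass after the adjustment for GC content and gene length either (median -0.12, camera adjusted p = 0.104).

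Knockdown of CNOT7 was compared with Control-1 to find the transcripts that respond to loss of a deadenylase, an enzyme that shortens poly(A) tails. EGR1, an immediate early transcription factor with an unstable mRNA, rose from 4.82 ± 0.27 RPKM to 46.8 ± 9.1 and 49.8 ± 3.4 (log2 change 3.2 ± 0.13, limma adjusted p = 1.17e-05), a fold of 9.19. LOX and LOXL2, lysyl oxidases that crosslink collagen, fell from 14.5 ± 0.14 to 1.74 ± 0.19 and 6.3 ± 1.1 RPKM and from 8.32 ± 0.31 to 1.31 ± 0.094 and 5.92 ± 1.1 RPKM (log2 changes -1.93 ± 0.1 and -1.36 ± 0.1, limma adjusted p = 5.62e-05 and 0.000347). Of the p53 targets, genes induced by the p53 tumour suppressor, 18 of 27 rose and none fell, or 20 rose adjusted over the list alone (median log2 change 0.53, camera adjusted p = 9.25e-11, and adjusted p = 0.053 with an estimated correlation). Examples were the apoptosis effector BAX, from 15.2 ± 0.25 to 36.6 ± 0.0042 and 24 ± 4 RPKM, and TRIAP1, 1.68-fold. Another was TP53I3, a quinone oxidoreductase, from 1.04 ± 0.087 to 3.6 ± 0.26 and 1.84 ± 0.18 RPKM. LNCTAM34A, a noncoding RNA antisense to the miR-34a host, rose 2.71-fold (log2 change 1.44 ± 0.19, limma adjusted p = 0.00235). Of 32 extracellular matrix and adhesion genes 17 fell and none rose, or 23 fell adjusted over the list alone (median log2 change -0.35, camera adjusted p = 5.98e-09, and adjusted p = 0.0633 with an estimated correlation). Of 31 hypoxia and glycolysis genes 16 fell and none rose, or 18 fell adjusted over the list alone (median -0.39, camera adjusted p = 1.26e-07, and adjusted p = 0.211 with an estimated correlation). Of the 23 aminoacyl-tRNA synthetases and partners, which charge tRNAs, 9 rose, or 14 adjusted over the list alone (camera adjusted p = 4.60e-06, and adjusted p = 0.129 with an estimated correlation). In total 1212 genes rose and 1544 fell, and most were not called with hairpin 2 alone. Of these 2756 genes, hairpin 1 alone called 2372 in the same direction and hairpin 2 alone 934. The basement membrane protein NID2 stood at 8.56 ± 0.36 RPKM in Control-1 and at 1.97 ± 0.16 and 7.72 ± 0.52 with hairpins 1 and 2. The glycolytic regulator PFKFB4 stood at 10 ± 0.28 against 1.99 ± 0.022 and 7.38 ± 0.65, and WARS1, which charges tryptophan tRNA, at 10.9 ± 0.44 against 27.7 ± 3 and 10.6 ± 0.073. With hairpin 2 alone, NID2, PFKFB4 and the matrix and hypoxia lists did not pass (adjusted p = 0.33, 0.084, 0.71 and 0.865). There COL4A1 stood at a log2 change of 0.2 and PFKP at 0.15 (limma adjusted p = 0.158 and 0.363), and the synthetases at a median of -0.14 (camera adjusted p = 0.664). CNOT7-sh2 replicate 1 followed gene GC content (Spearman rho = 0.62 across genes, which are not independent replicates), unlike its partner (-0.14). The count was 6527 without it, 8032 without replicate 2, 1617 and 1720 without CNOT7-sh1 replicate 1 or 2, 556 without ctrl-2, 394 without ctrl-3 and 61 with the compared groups alone. In that last fit BAX, LNCTAM34A and WARS1 did not pass (limma adjusted p = 0.0507, 0.0608 and 0.0608). Transcripts of short noncoding genes among the largest changes, such as SNORD3A (a fold of 3.13) and MT-TP (log2 change -1.57 ± 0.29), did not hold without ctrl-3 (limma adjusted p = 0.126 and 0.105). The SNORD3 copies can share reads.

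Knockdown of UBAP2L, a protein needed for stress granules, was compared with Control-1. ACTA2, smooth muscle actin, rose from 2.64 ± 0.086 RPKM to 11.3 ± 0.58 and 3.95 ± 0.034 (log2 change 1.2 ± 0.09, limma adjusted p = 0.0014). EGR1 rose from 4.82 ± 0.27 to 10.7 ± 0.48 and 10.7 ± 0.41 RPKM (log2 change 1.07 ± 0.13, limma adjusted p = 0.00785). The transcription factor SOX4 fell from 64.3 ± 1.6 to 37.1 ± 0.18 and 33.1 ± 0.74 RPKM (log2 change -0.86 ± 0.08, limma adjusted p = 0.00532), with the posterior homeobox genes HOXD13 (1.92-fold) and HOXA13 (1.78-fold). LOX, at 14.5 ± 0.14 RPKM in Control-1, fell to 12.6 ± 0.53 and 3.99 ± 0.2, and UVRAG, an autophagy factor, fell 1.77-fold. In all, 150 genes rose and 148 fell. ACTA2 also stood among 6 measured markers of other cell types, of which 1 rose, or 2 adjusted over the list alone (camera adjusted p = 0.0244, and adjusted p = 0.521 with an estimated correlation). Of 27 p53 targets 9 rose and none fell, or 12 rose adjusted over the list alone (median log2 change 0.37, camera adjusted p = 7.95e-10, and adjusted p = 0.0721 with an estimated correlation). They included BTG2, an antiproliferative partner of deadenylases, from 9.84 ± 0.12 to 31.9 ± 0.2 and 9.98 ± 1.2 RPKM. Others were the stress cytokine GDF15, from 1.47 ± 0.056 to 5.1 ± 0.056 and 1.63 ± 0.061 RPKM, and TP53I3, 2.06-fold. With hairpin 2 alone the p53 list and BTG2, GDF15 and TP53I3 did not pass (adjusted p = 0.796, 0.891, 0.552 and 0.0728), nor did HOXD13, RPS27L and the markers of other cell types (limma adjusted p = 0.0867 and 0.0592, camera adjusted p = 0.473). LOX did not pass with hairpin 1 alone (log2 change -0.22, limma adjusted p = 0.393). Of 39 G1/S and E2F targets 6 fell and none rose, or 11 fell adjusted over the list alone (camera adjusted p = 1.35e-07, and adjusted p = 0.254 with an estimated correlation). The replication helicase subunit MCM3 went from 90.9 ± 0.87 to 67.4 ± 0.11 and 71.7 ± 0.2 RPKM. Of 103 nuclear-encoded respiratory chain genes 3 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 1.29e-10, and adjusted p = 0.521 with an estimated correlation). Of 82 cytosolic ribosomal proteins 2 rose (the same 2 adjusted over the list alone), among them RPS27L, itself a p53 target (camera adjusted p = 2.97e-08, and adjusted p = 0.551 with an estimated correlation). The UBAP2L-sh2 libraries followed gene length downward (Spearman rho -0.27 and -0.23 across genes), and after adjustment for GC content and gene length that list still passed camera, at a median of 0.12. Without ctrl-2 or ctrl-3 only UBAP2L itself passed among all genes (SOX4, limma adjusted p = 0.118 and 0.0894, and EGR1, 0.123 and 0.128), and no named gene other than UBAP2L held in every such fit. The count was 52 and 35 without UBAP2L-sh1 replicate 1 or 2, 38 and 79 without UBAP2L-sh2 replicate 1 or 2, 3277 without CNOT7-sh2 replicate 1 and 3773 with the compared groups alone.

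**Figure D2:**
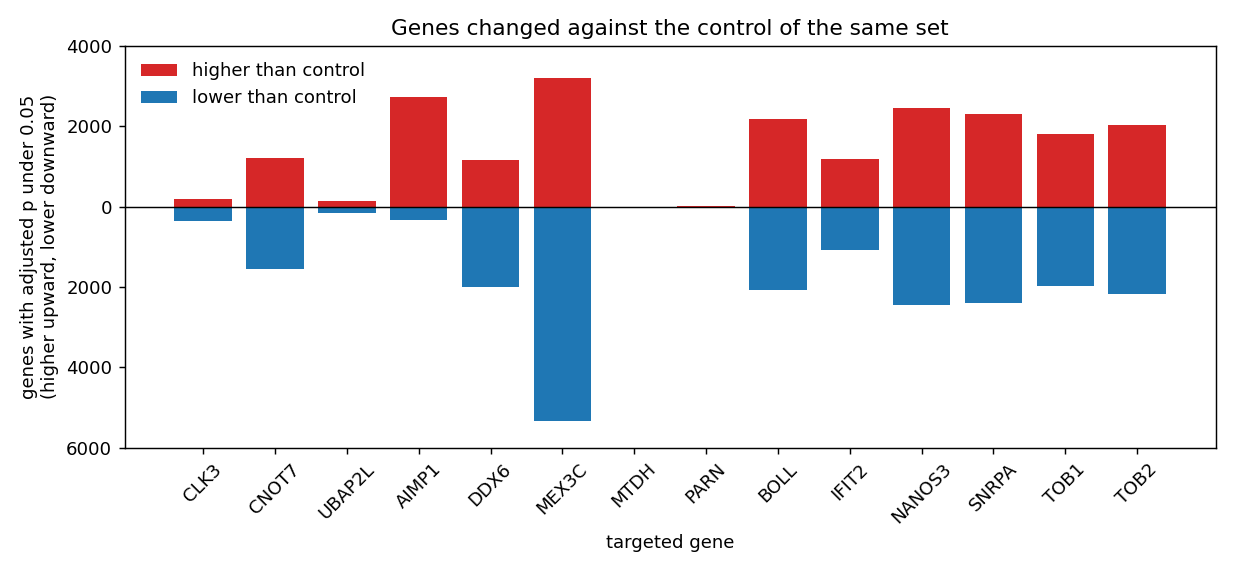
Number of genes with a limma adjusted p under 0.05 against the control of the same table, for each targeted gene on the horizontal axis, with genes higher than control drawn upward in red and genes lower than control downward in blue. The counts run from 0 for MTDH knockdown to 3199 higher and 5331 lower for MEX3C knockdown.

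Knockdown of AIMP1, a scaffold of the multisynthetase complex that charges tRNAs, was compared with Control-2. HSP90AA1, the inducible cytosolic HSP90 chaperone, rose from 7.49 ± 0.92 RPKM to 30.5 ± 4.3 and 28 ± 2.9 (log2 change 1.95 ± 0.16, limma adjusted p = 1.04e-05), together with 3 of its processed copies, with which it can share reads. HSPD1, the mitochondrial chaperonin, rose from 13 ± 2.7 to 41.4 ± 4.6 and 35.4 ± 2.3 RPKM (log2 change 1.6 ± 0.12, limma adjusted p = 1.04e-05). EIF2A, a translation initiation factor, rose 3.2-fold, and LTV1, a factor of small ribosomal subunit assembly, 3.03-fold. C14orf93 fell from 2.46 ± 0.14 to 0.667 ± 0.06 and 0.615 ± 0.0092 RPKM (log2 change -1.32 ± 0.11, limma adjusted p = 1.04e-05). TBC1D13, a GTPase-activating protein for Rab proteins, fell from 18.5 ± 0.25 to 8.35 ± 0.78 and 10.3 ± 0.96 RPKM, and DNMT3B, a de novo DNA methyltransferase, 1.79-fold. Changes ran mostly upward, with 2729 genes higher and 342 lower of 11993. No gene differed between the hairpins after adjustment by limma (531 at an unadjusted p under 0.05). Of 41 ribosome biogenesis genes 21 rose and none fell, or 22 rose adjusted over the list alone (median log2 change 0.5, camera adjusted p = 0.00744, and adjusted p = 0.812 with an estimated correlation). They included the nucleolar proteins NPM1, from 37.2 ± 6.2 to 118 ± 1.9 and 97.5 ± 7.2 RPKM, and GNL3, 2.43-fold. Of 31 G2/M genes 17 rose and none fell, or 17 and 1 adjusted over the list alone (camera adjusted p = 0.00744, and adjusted p = 0.812 with an estimated correlation). Among them were the spindle factors TPX2 (1.91-fold) and NUSAP1 (2.55-fold) and the checkpoint kinase BUB1 (2.35-fold). Of 18 SR proteins and CLK kinases 11 rose, or 12 adjusted over the list alone (camera adjusted p = 0.00744, and adjusted p = 0.812 with an estimated correlation), the splicing factor SRSF1 going from 8.64 ± 1.7 to 16.3 ± 1.1 and 14.2 ± 0.27 RPKM. Of 15 stress granule proteins 10 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0196, and adjusted p = 0.812 with an estimated correlation). G3BP2 was 2.29-fold and DDX3X 2.16-fold higher. The aminoacyl-tRNA synthetases and their complex, the group AIMP1 belongs to, did not pass the list test (camera adjusted p = 0.176), though 11 of 22 members rose and 1 fell, or 11 and 2 adjusted over the list alone. All 4 AIMP1 libraries followed gene GC content downward (Spearman rho from -0.56 to -0.43 across genes). After the adjustment for GC content and gene length the G2/M, SR protein and stress granule lists no longer passed (camera adjusted p = 0.137, 0.828 and 0.264). The count was 1479 without control ctrl-1-2.

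Knockdown of DDX6, an RNA helicase of P-bodies that acts in translational repression and decapping, was also compared with Control-2. TNFRSF12A, the TWEAK receptor, rose from 13.1 ± 0.44 RPKM to 49.7 ± 2.4 and 24.5 ± 0.42 (log2 change 1.42 ± 0.11, limma adjusted p = 2.6e-05). CMTM3 rose from 7.93 ± 0.059 to 16.3 ± 0.11 and 17.3 ± 0.14 RPKM (log2 change 1.08 ± 0.08, limma adjusted p = 2.6e-05). The small heat shock protein CRYAB rose from 0.646 ± 0.13 to 1.25 ± 0.35 and 6.35 ± 0.88 RPKM, CSRNP1 2.43-fold and the glypican GPC2 2.21-fold. STEEP1, which helps STING leave the endoplasmic reticulum, fell from 13.8 ± 1.2 to 3.01 ± 0.019 and 9.63 ± 1.8 RPKM (log2 change -1.22 ± 0.1, limma adjusted p = 2.6e-05). NAT10, the RNA cytidine acetyltransferase, fell from 12.5 ± 0.78 to 4.14 ± 0.41 and 6.44 ± 1.8 RPKM (log2 change -1.17 ± 0.12, limma adjusted p = 0.000195), and PPP1R10 2.14-fold. In all, 1153 genes rose and 2000 fell. Of 16 replication-dependent histone genes 6 rose and none fell (also 6 adjusted over the list alone, median log2 change 0.4, camera adjusted p = 7.35e-04, and adjusted p = 0.749 with an estimated correlation). H2BC13 was 1.75-fold higher and the identical copies H3C14 and H3C15 each 1.62-fold higher. Of 27 immediate early genes with AU-rich elements 9 rose and 1 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00191, and adjusted p = 0.749 with an estimated correlation). Among them were JUNB, an AP-1 subunit, from 13.8 ± 0.75 to 23 ± 0.15 and 19.1 ± 0.67 RPKM, and IER3, 1.72-fold. Of 30 hypoxia and glycolysis genes 10 rose (the same count adjusted over the list alone), the enolase ENO2 from 25.3 ± 1.4 to 49.2 ± 3.2 and 50.4 ± 1.5 RPKM (camera adjusted p = 0.0022, and adjusted p = 0.749 with an estimated correlation). Of 15 mitochondrial genome transcripts 10 fell and none rose, or 12 fell adjusted over the list alone (median -0.62, camera adjusted p = 0.00121, and adjusted p = 0.749 with an estimated correlation). The ribosomal RNA MT-RNR1 went from 813 ± 7 to 555 ± 47 and 435 ± 46 RPKM. Of 15 stress granule proteins 6 fell and none rose, or 10 fell adjusted over the list alone (camera adjusted p = 0.00502, and adjusted p = 0.749 with an estimated correlation). The decapping and P-body genes did not pass (camera adjusted p = 0.463). The DDX6 libraries followed GC content with Spearman rho from 0.05 to 0.36 across genes. The count was 2097 and 1987 without DDX6-sh1 or DDX6-sh2 replicate 2, 728 without ctrl-1-1, 1190 without ctrl-1-2 and 1098 with hairpin 2 alone. There the mitochondrial list kept passing but DUSP1 and ALDH9A1 did not (limma adjusted p = 0.0747 and 0.086). With hairpin 1 alone the mitochondrial list did not pass (camera adjusted p = 0.252).

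Knockdown of MEX3C, an RNA-binding ubiquitin ligase, gave the highest count of the 14 comparisons, with 3199 genes higher and 5331 lower than in Control-2. On the RPKM scale as deposited the split was 2213 higher and 6645 lower. The factors differed most here (log2 factors of -0.406 and -0.26 in MEX3C-sh2 against 0.17 in DDX6-sh2 replicate 1 and 0.104 in ctrl-1-1), and directions are relative to that scaling. PFN2, an actin-binding profilin, fell from 31.2 ± 0.54 RPKM to 14.9 ± 2.2 and 1.88 ± 0.31 (log2 change -2.19 ± 0.11, limma adjusted p = 2.37e-07). LDHB, a lactate dehydrogenase subunit, fell from 91 ± 16 to 28 ± 5.1 and 18.6 ± 1.9 RPKM (log2 change -1.74 ± 0.13, limma adjusted p = 2.54e-06), with KIAA1191 3.71-fold lower and the centromere protein OIP5 3.31-fold. LGALS1, a galectin, rose from 15 ± 1.5 to 34.3 ± 4.6 and 60.2 ± 12 RPKM (log2 change 1.79 ± 0.17, limma adjusted p = 7.87e-06). PHLDA3, a p53-induced inhibitor of AKT, rose from 17.2 ± 0.26 to 33.3 ± 5.2 and 56.4 ± 2.1 RPKM (log2 change 1.53 ± 0.11, limma adjusted p = 2.54e-06), with GDF15 2.95-fold higher, the synuclein SNCG 3.25-fold and the proapoptotic BIK 3.2-fold. Of 18 SR proteins and CLK kinases 16 fell and none rose (the same adjusted over the list alone, median log2 change -0.57, camera adjusted p = 0.00733, and adjusted p = 0.633 with an estimated correlation). SRSF3 fell from 32.5 ± 3.4 to 17.2 ± 0.11 and 10.5 ± 0.12 RPKM and CLK2 2.26-fold. Of 18 cytosolic heat shock genes 14 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.0164, and adjusted p = 0.633 with an estimated correlation), STIP1, a cochaperone, being 2.1-fold lower. Of 37 G1/S and E2F targets 28 fell and 5 rose, the same adjusted over the list alone (camera adjusted p = 0.0164, and adjusted p = 0.633 with an estimated correlation). TYMS, thymidylate synthase, fell from 34 ± 3.2 to 19.9 ± 3.1 and 10.1 ± 0.54 RPKM. Of 15 stress granule proteins 14 fell, the same adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.633 with an estimated correlation), among them YBX1 (1.63-fold). Of 16 interferon-stimulated genes 10 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.633 with an estimated correlation). All 4 MEX3C libraries followed gene GC content upward (Spearman rho from 0.44 to 0.55 across genes). After the adjustment for GC content and gene length the SR protein and stress granule lists no longer passed (camera adjusted p = 0.304 and 0.295). The interferon list did not pass with hairpin 1 alone (camera adjusted p = 0.0665), where 5312 genes were called.

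Knockdown of MTDH, an RNA-binding protein of the endoplasmic reticulum and nuclear membrane, was compared with Control-3. No gene passed in limma, 873 genes had an unadjusted p under 0.05, and limma voom on recovered reads called 0 as well. SQLE, squalene epoxidase of sterol synthesis, was among the 3 genes with the smallest p, at 94.3 ± 0.99 RPKM in Control-3 against 37.5 ± 6.1 and 56.4 ± 0.68. It lay below both controls in 4 of 4 libraries (log2 change -0.97 ± 0.12, limma adjusted p = 0.19). LRRC23 stood at 3.24 ± 0.088 RPKM against 1.09 ± 0.19 and 1.79 ± 0.069. NANOS3 was the other, at 5.2 and 15.9 RPKM in the Control-3 libraries and under 0.5 in every knockdown library of that table, and the source of these reads was not tested. The cholesterol biosynthesis list (31 measured) was lower, with a median log2 change of -0.29, none past the test over all genes and 8 lower adjusted over the list alone (camera adjusted p = 3.27e-12, and adjusted p = 0.0837 with an estimated correlation). Its members SCD, stearoyl-CoA desaturase, and FDFT1, squalene synthase, stood at 100 ± 2.6 RPKM against 49.8 ± 0.94 and 70 ± 2, and at 35.4 ± 1.5 against 19.1 ± 0.13 and 33.3 ± 0.53. Immediate early genes (26 measured) were higher with 5 past the test adjusted over the list alone and none over all genes (camera adjusted p = 1.13e-05, and adjusted p = 0.333 with an estimated correlation). EGR1 stood at 0.881 ± 0.18 RPKM against 1.25 ± 0.39 and 2.06 ± 0.066. Replication-dependent histones (17 measured) were higher with 1 past the test adjusted over the list alone and none over all genes (camera adjusted p = 1.21e-07, and adjusted p = 0.333 with an estimated correlation). The linker histone H1-2 stood at 54.3 ± 8.5 RPKM against 51.2 ± 10 and 113 ± 3.3. With hairpin 1 alone this list stood at a median of -0.05 (camera adjusted p = 0.615), and the immediate early list did not pass (camera adjusted p = 0.346). MTDH-sh1 replicate 1, the shallowest library at 14.4 M reads, followed GC content downward (Spearman rho = -0.74 across genes) where its partner stood at 0.35. The count was 1095 without it, 7645 without its partner, 1 without either control and 1 with hairpin 1 alone. The cholesterol list did not pass with hairpin 2 alone (median 0.01, camera adjusted p = 0.287), and the immediate early and histone lists did not without MTDH-sh1 replicate 2 (camera adjusted p = 0.206 and 0.0507).

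Knockdown of PARN, a deadenylase that trims the 3′ ends of small nucleolar RNAs and of telomerase RNA, was compared with Control-3. TERC, the telomerase RNA, rose from 0.27 ± 0.023 RPKM to 2.11 ± 0.18 and 5.06 ± 0.73 (log2 change 2.31 ± 0.19, limma adjusted p = 0.0235). As a noncoding RNA in libraries from an mRNA kit, it may have changed in capture rather than amount, which was not tested. LNCTAM34A rose from 1.65 ± 0.041 to 3.49 ± 0.31 and 7.07 ± 0.23 RPKM (log2 change 1.39 ± 0.11, limma adjusted p = 0.0189), and TP53I3 from 1.02 ± 0.16 to 2.69 ± 0.27 and 2.67 ± 0.13 RPKM (log2 change 1.1 ± 0.11, limma adjusted p = 0.0381). INPP5D, an inositol phosphatase, rose 2.23-fold and BCDIN3D, an RNA methyltransferase, 1.91-fold, while PMP22, a myelin protein, fell from 6.35 ± 0.34 to 2.31 ± 0.029 and 3.8 ± 0.061 RPKM. Of 15697 genes tested, 5 rose and 4 fell. The lower ones were PARN, PMP22, NANOS3 and CKS1B, a cyclin-dependent kinase subunit outside the naming rule and named after its values were seen, at 83.2 RPKM in Control-3 and a mean of 50.3 RPKM in the knockdown. Of 26 p53 targets 1 rose and none fell, or 7 rose adjusted over the list alone (median log2 change 0.37, camera adjusted p = 7.32e-10), a call that held with an estimated correlation (camera adjusted p = 0.0179). BTG2 stood at 8.64 ± 0.031 RPKM against 22.5 ± 2 and 10.1 ± 0.33 (limma adjusted p = 0.102). The list of snoRNAs, scaRNAs and telomerase RNA (77 measured) was lower with a median log2 change of -0.54, against the direction of TERC, its only member to rise. It also held with an estimated correlation (camera adjusted p = 1.77e-06 and 0.0179), with 1 higher and 1 lower adjusted over the list alone. Cytosolic ribosomal proteins (82 measured, median 0.24) and mitochondrial genome transcripts (15 measured, median 0.37) were higher, with camera adjusted p = 8.57e-14 and 3.80e-08, and adjusted p = 0.301 and 0.42 with an estimated correlation. No member of either passed over all genes, and 0 and 6 passed adjusted over the list alone. The 4 PARN libraries followed gene length downward (Spearman rho from -0.29 to -0.14 across genes) and GC content upward (0.08 to 0.47). After adjustment for both these lists still passed, at medians of 0.24 and 0.3 (highest camera adjusted p = 0.00627). None of the 9 calls held in every fit that left out 1 library. The 6 without a PARN or control library kept the wide MTDH-sh1 pair in their pooled errors (partner SD 0.833, against 0.254 and 0.202 for PARN). The count was 0 in each fit without 1 PARN library and without ctrl-1-2, 1 without ctrl-1-1, 4009 (all 9 genes among them) without MTDH-sh1 replicate 1. It was 2654 with the compared groups alone, 143 with hairpin 1 alone, 4 without the expression filter and 2 with a pseudocount of 0.1. INPP5D did not pass with hairpin 1 alone (limma adjusted p = 0.134), nor TP53I3, BCDIN3D and PMP22 with hairpin 2 alone (0.085, 0.12 and 0.199).

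**Figure D3:**
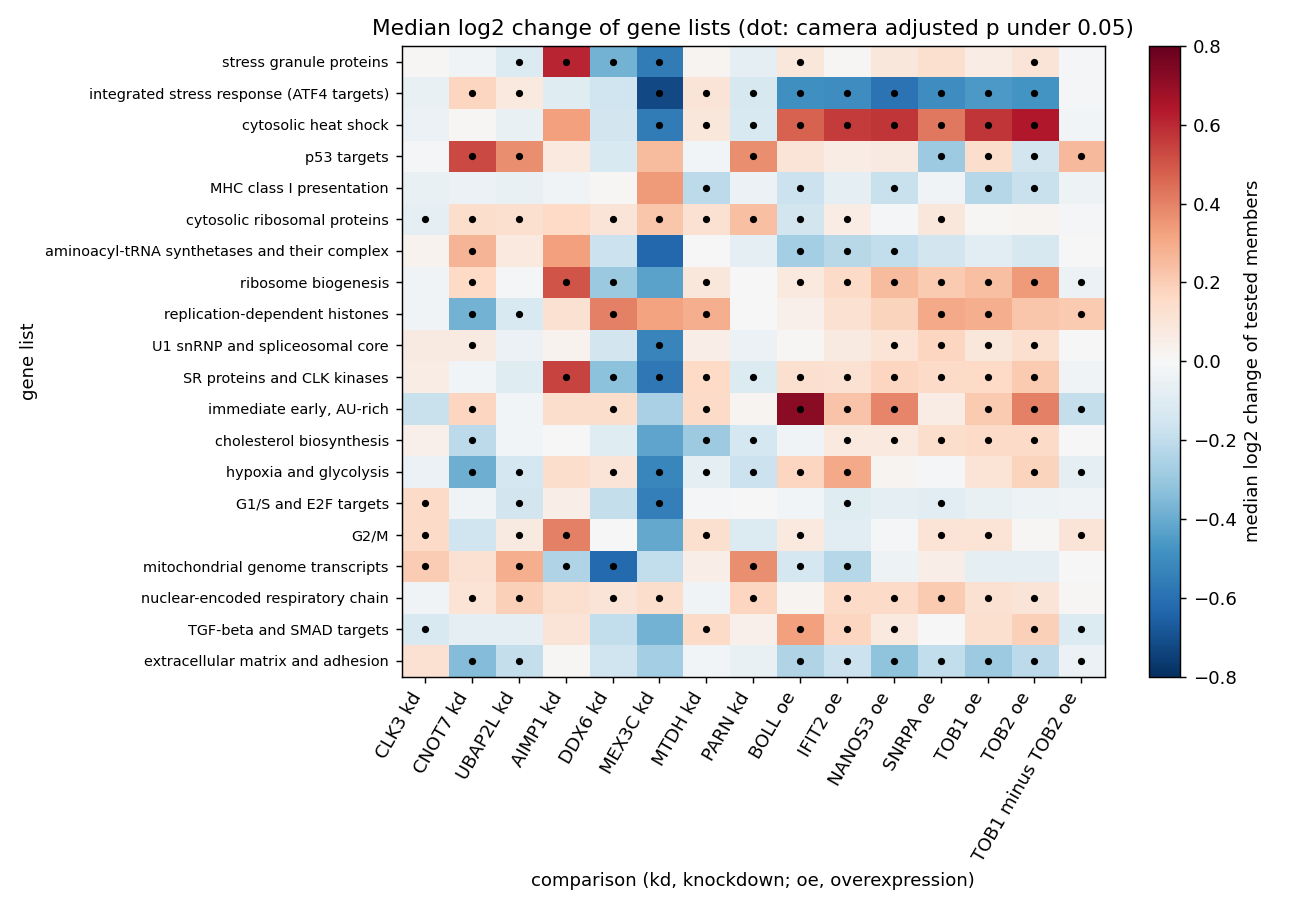
Median log2 change of the measured members of 20 gene lists (vertical axis) in the 15 comparisons (horizontal axis, kd for knockdown and oe for overexpression), as colour from -0.8 in blue to 0.8 in red, with a dot where the camera adjusted p with the preset correlation was under 0.05. Heat shock genes were higher and ATF4 targets lower in all 6 overexpression columns, and of the 172 dotted results over all 35 lists 4 held with an estimated correlation.

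The overexpression groups were compared with the FLAG libraries. BOLL is a germ cell RNA-binding protein of the DAZ family. With BOLL overexpression, HSPA6, a strictly inducible HSP70, rose from 0.134 ± 0.05 to 13.6 ± 0.17 RPKM (log2 change 4.45 ± 0.06, limma adjusted p = 2.61e-11). HSPA1A, the major inducible HSP70, rose from 92.7 ± 23 to 874 ± 172 RPKM (log2 change 3.24 ± 0.21, limma adjusted p = 2.09e-05), and DNAJB1, its HSP40 partner, from 15.9 ± 2.3 to 63.4 ± 4.4 RPKM. HSPA1A can share reads with HSPA1B and HSPA1L, and HSPA6 with HSPA7, and these copies moved with them. EGR1 rose from 1.78 ± 0.04 to 9.64 ± 0.27 RPKM (log2 change 2.15 ± 0.09, limma adjusted p = 1.15e-06). PCK2, mitochondrial phosphoenolpyruvate carboxykinase and an ATF4 target, fell from 36.4 ± 6.4 to 16.6 ± 3.9 RPKM (log2 change -1.12 ± 0.19, limma adjusted p = 0.00267). G0S2, an inhibitor of lipolysis, was 2.59-fold lower and CHAC1, which degrades glutathione, 2.84-fold lower. In total 2183 genes rose and 2080 fell of 16118. Of 31 immediate early genes 27 rose and 1 fell (the same adjusted over the list alone, median log2 change 0.72, camera adjusted p = 1.81e-16, and adjusted p = 0.141 with an estimated correlation). Among them were the phosphatase DUSP1 (3.15-fold) and the matricellular protein CCN1 (2.89-fold). Of 20 cytosolic heat shock genes 17 rose and none fell, or 18 rose adjusted over the list alone (median 0.47, camera adjusted p = 1.12e-13, and adjusted p = 0.152 with an estimated correlation). Of 40 ATF4 targets, the genes of the integrated stress response, 27 fell and 2 rose, or 29 and 2 adjusted over the list alone (median -0.49, camera adjusted p = 7.87e-10, and adjusted p = 0.325 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, went from 120 ± 9 to 72.7 ± 7.9 RPKM. Of 82 cytosolic ribosomal proteins 24 fell and 2 rose, or 33 and 2 adjusted over the list alone (median -0.15, camera adjusted p = 1.10e-07, and adjusted p = 0.592 with an estimated correlation). Of 28 decapping and P-body genes 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00171, and adjusted p = 0.0953 with an estimated correlation). The count was 2488 and 1533 without FLAG replicate 1 or 2 and 1400 with the compared groups alone. Without FLAG replicate 2 the calls of G0S2 and CHAC1 ended (limma adjusted p = 0.0867 and 0.164), and that of CHAC1 also without FLAG replicate 1 or BOLL replicate 1 (0.083 and 0.223). Neither passed with the compared groups alone (limma adjusted p = 0.0816 and 0.119).

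With overexpression of IFIT2, an interferon-induced RNA-binding protein, HSPA6 rose to 48.2 ± 2.8 RPKM (log2 change 6.27 ± 0.06, limma adjusted p = 7.58e-13) and HSPA1A to 693 ± 88 RPKM (log2 change 2.94 ± 0.21, limma adjusted p = 6.57e-05). ANKRD1, a target of the YAP coactivator, rose from 0.134 ± 0.019 to 2.13 ± 0.26 RPKM (log2 change 2.05 ± 0.1, limma adjusted p = 2.88e-06). G0S2 fell 3.79-fold to 2.21 ± 0.13 RPKM, PCK2 2.36-fold to 14.7 ± 0.45 RPKM and SLC6A9, a glycine transporter, 2.25-fold. All 20 heat shock genes rose, also adjusted over the list alone (median log2 change 0.56, camera adjusted p = 2.26e-22, and adjusted p = 0.291 with an estimated correlation). The cochaperone BAG3 went from 12.9 ± 0.33 to 29.2 ± 1.2 RPKM. Of 40 ATF4 targets 31 fell and 2 rose, or 33 and 3 adjusted over the list alone (median -0.5, camera adjusted p = 2.86e-12, and adjusted p = 0.361 with an estimated correlation). Of 32 hypoxia and glycolysis genes 14 rose and none fell, or 18 rose adjusted over the list alone (median 0.3, camera adjusted p = 1.24e-08, and adjusted p = 0.365 with an estimated correlation). Among them were the prolyl hydroxylase EGLN3 (1.85-fold), the glucose transporter SLC2A1 (1.75-fold) and hexokinase HK2 (1.66-fold). Of 107 respiratory chain genes 31 rose and 3 fell, or 45 and 4 adjusted over the list alone (camera adjusted p = 6.19e-09, and adjusted p = 0.361 with an estimated correlation). The interferon-stimulated genes, the group IFIT2 belongs to, did not pass the list test without IFIT2 itself (camera adjusted p = 0.0544), with none of 22 higher and 4 lower, the same adjusted over the list alone. In total 1195 genes rose and 1084 fell, against 1047 and 1431 on the RPKM scale as deposited. The count was 593 and 233 without IFIT2 replicate 1 or 2, 907 without FLAG replicate 1 and 51 without FLAG replicate 2. Without FLAG replicate 2 G0S2, PCK2, SLC6A9, EGLN3, SLC2A1 and HK2 did not pass (limma adjusted p = 0.0805, 0.0728, 0.124, 0.0709, 0.0998 and 0.103). HSPA6, HSPA1A and ANKRD1 held in every fit that left out 1 library.

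NANOS3 is a germ cell RNA-binding protein that recruits deadenylases. Its overexpression raised HSPA1A to 538 ± 89 RPKM (log2 change 2.55 ± 0.21, limma adjusted p = 0.000196) and HSPA6 to 5.98 ± 0.13 RPKM (log2 change 3.34 ± 0.06, limma adjusted p = 5.06e-10). The constitutive HSP70 gene HSPA8 rose from 107 ± 14 to 301 ± 0.23 RPKM (log2 change 1.49 ± 0.19, limma adjusted p = 0.000957). G0S2 fell from 10.1 ± 2.8 to 1.96 ± 0.59 RPKM (log2 change -2.1 ± 0.31, limma adjusted p = 0.00163), PCK2 2.94-fold, SLC6A9 2.8-fold and SLC7A11, the cystine transporter, 2.55-fold. All 20 heat shock genes rose, also adjusted over the list alone (median log2 change 0.57, camera adjusted p = 1.97e-15, and adjusted p = 0.495 with an estimated correlation). Of 44 ribosome biogenesis genes 33 rose and 1 fell, or 36 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 1.94e-12, and adjusted p = 0.495 with an estimated correlation). NOP16, a nucleolar protein, went from 11.4 ± 0.89 to 22.9 ± 0.25 RPKM. Of 40 ATF4 targets 33 fell and 1 rose, or 35 and 1 adjusted over the list alone (median -0.59, camera adjusted p = 1.94e-12, and adjusted p = 0.495 with an estimated correlation). The proapoptotic factor DDIT3 (CHOP) went from 24.6 ± 3.4 to 12 ± 0.46 RPKM. Of 30 matrix and adhesion genes 23 fell, also adjusted over the list alone (median -0.32, camera adjusted p = 5.97e-09, and adjusted p = 0.495 with an estimated correlation). The type VI collagens COL6A1 and COL6A2 fell by 1.47-fold and 1.53-fold. In total 2443 genes rose and 2462 fell. The count was 2929 and 1837 without FLAG replicate 1 or 2 and 2808 with the compared groups alone. SLC7A11 did not pass without FLAG replicate 2 or NANOS3 replicate 1 (limma adjusted p = 0.099 and 0.0672).

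SNRPA, a protein of the U1 small nuclear ribonucleoprotein, was overexpressed in the next group. There HSPA6 stayed at 0.174 and 0.185 RPKM against 0.17 and 0.099 in the FLAG libraries. HSPA1A rose to 323 ± 77 RPKM (log2 change 1.84 ± 0.21, limma adjusted p = 0.000564) and DNAJA1, an HSP40, from 43.3 ± 6.2 to 87.4 ± 12 RPKM. DDIT3 fell to 10.5 ± 0.97 RPKM (log2 change -1.15 ± 0.11, limma adjusted p = 0.000336), PCK2 2.41-fold and NUPR1, a stress-induced chromatin protein, from 5.68 ± 2 to 1.69 ± 0.67 RPKM (log2 change -1.46 ± 0.25, limma adjusted p = 0.00267). Of 40 ATF4 targets 32 fell and 1 rose, or 37 and 1 adjusted over the list alone (median log2 change -0.5, camera adjusted p = 5.32e-13, and adjusted p = 0.422 with an estimated correlation). Of 20 heat shock genes 17 rose, also adjusted over the list alone (median 0.42, camera adjusted p = 1.01e-10, and adjusted p = 0.422 with an estimated correlation). Of 107 respiratory chain genes 51 rose and 3 fell, or 56 and 3 adjusted over the list alone (median 0.21, camera adjusted p = 1.01e-10, and adjusted p = 0.422 with an estimated correlation). The complex IV subunit NDUFA4 went from 31.2 ± 0.57 to 38.9 ± 0.47 RPKM. Both libraries followed gene length and GC content downward (Spearman rho -0.19 and -0.24, and -0.35 and -0.22), and after adjustment for both the list still passed camera, at a median of 0.18. Of 28 genes of the U1 snRNP and spliceosomal core other than SNRPA 12 rose and 1 fell, or 16 and 2 adjusted over the list alone (median 0.17, camera adjusted p = 1.22e-04, and adjusted p = 0.422 with an estimated correlation). Of 27 p53 targets 15 fell and 3 rose, or 17 and 3 adjusted over the list alone (median -0.29, camera adjusted p = 2.47e-05, and adjusted p = 0.133 with an estimated correlation). In total 2305 genes rose and 2410 fell, against 1830 and 3048 on the RPKM scale as deposited. Apart from SNRPA itself, the highest folds belonged to copies of the 7SK and U3 RNAs, which can share reads. RN7SKP80 (8.02-fold) and SNORD3A (3.83-fold) did not pass in any fit that left out 1 compared library (limma adjusted p from 0.102 to 0.151 and from 0.0611 to 0.162). RN7SKP48 was lost in 2 of those 4 fits, and RN7SKP185 and SNORD3B-2 in 3 (highest limma adjusted p = 0.0665, 0.1 and 0.12). The count was 1748 without SNRPA replicate 2 and 2905 and 1857 without FLAG replicate 1 or 2.

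**Figure D4:**
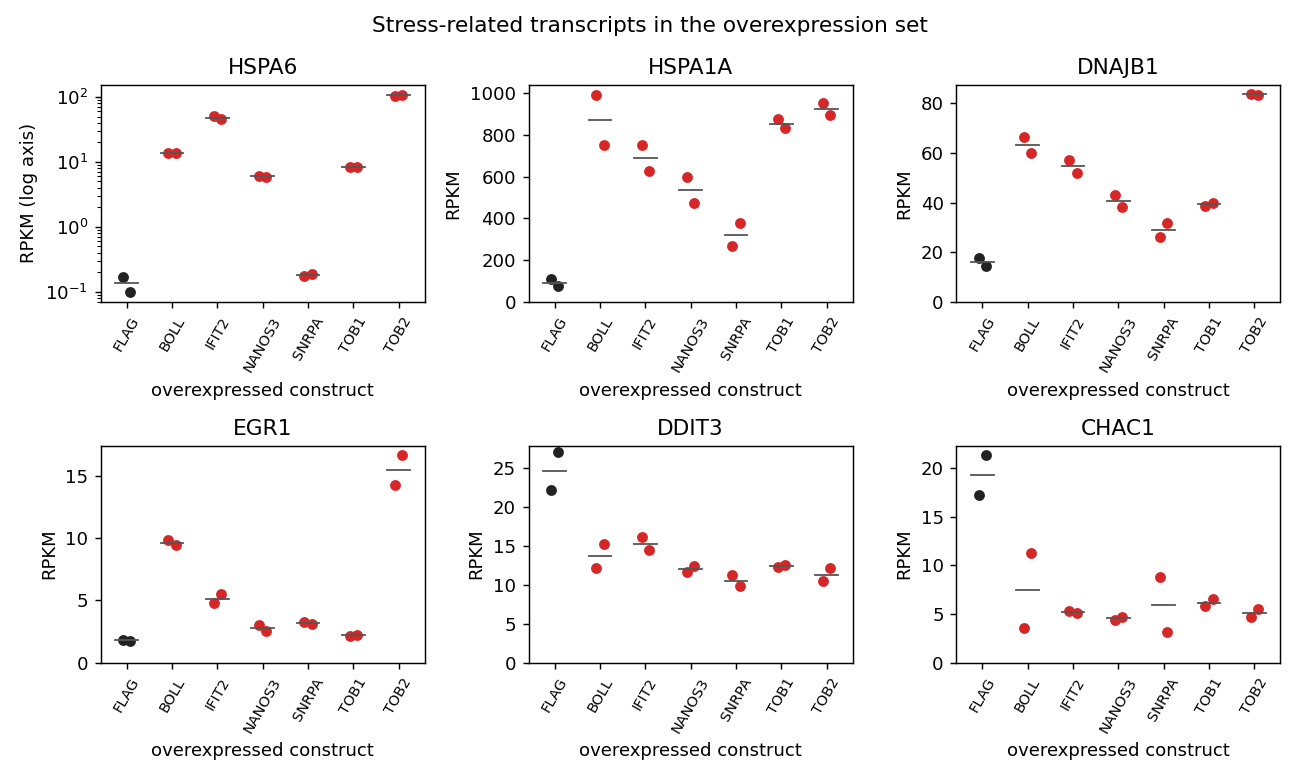
RPKM of 6 stress-related genes (vertical axes, log for HSPA6 and linear from 0 for the others) in the FLAG control libraries (black points) and the 6 overexpression groups (red points), with lines at group means. HSPA6 reached 105 ± 3.7 RPKM with TOB2 and 48.2 ± 2.8 with IFIT2, DDIT3 stood at 24.6 ± 3.4 RPKM in the FLAG libraries, and both EGR1 and DNAJB1 had their highest mean with TOB2.

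TOB1 and TOB2 are antiproliferative proteins that bring the CCR4-NOT deadenylase to mRNAs. With TOB1, HSPA1A rose to 856 ± 34 RPKM (log2 change 3.27 ± 0.21, limma adjusted p = 3.07e-05), HSPA6 to 8.38 ± 0.13 RPKM and HSPA8 to 307 ± 12 RPKM. ANKRD1 rose to 5.43 ± 0.64 RPKM (log2 change 3.25 ± 0.1, limma adjusted p = 2.71e-08). G0S2 fell to 2.13 ± 0.23 RPKM (log2 change -1.95 ± 0.31, limma adjusted p = 0.00274), SLC6A9 2.58-fold and PCK2 2.38-fold. Of 20 heat shock genes 19 rose, also adjusted over the list alone (median log2 change 0.57, camera adjusted p = 1.13e-19, and adjusted p = 0.197 with an estimated correlation). Of 44 ribosome biogenesis genes 32 rose and 1 fell, or 36 and 1 adjusted over the list alone (median 0.24, camera adjusted p = 1.13e-13, and adjusted p = 0.422 with an estimated correlation). Among them were UTP3 (1.57-fold) and RRS1 (1.65-fold), factors of ribosomal subunit assembly. Of 40 ATF4 targets 27 fell and 3 rose, or 32 and 3 adjusted over the list alone (median -0.46, camera adjusted p = 4.25e-10, and adjusted p = 0.422 with an estimated correlation). Of 30 matrix genes 19 fell, or 22 adjusted over the list alone (median -0.29, camera adjusted p = 4.04e-09, and adjusted p = 0.422 with an estimated correlation). In total 1816 genes rose and 1968 fell, against 1353 and 2678 on the RPKM scale as deposited. The count was 2051 and 1092 without TOB1 replicate 1 or 2 and 1990 and 1092 without FLAG replicate 1 or 2. Of the 24 named genes that passed only CHAC1 (2.88-fold lower) was lost in a fit that left out 1 library (limma adjusted p from 0.088 to 0.175).

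With TOB2, HSPA6 rose to 105 ± 3.7 RPKM (log2 change 7.43 ± 0.06, limma adjusted p = 1.31e-13) and HSPA1A to 925 ± 41 RPKM (log2 change 3.4 ± 0.21, limma adjusted p = 1.1e-05). EGR1 rose to 15.5 ± 1.7 RPKM (log2 change 2.87 ± 0.09, limma adjusted p = 4.23e-08), and ARC, a neuronal immediate early gene, from 1.07 ± 0.0036 to 9.81 ± 0.33 RPKM. DUSP1 rose from 8.13 ± 1 to 40.4 ± 0.0099 RPKM, and ANKRD1 to 5.61 ± 0.16 RPKM. PCK2 fell to 12.8 ± 0.78 RPKM (log2 change -1.4 ± 0.19, limma adjusted p = 0.00121) and G0S2 3.65-fold. All 20 heat shock genes rose, also adjusted over the list alone (median log2 change 0.64, camera adjusted p = 1.18e-20, and adjusted p = 0.348 with an estimated correlation), among them DNAJB1, to 83.8 ± 0.36 RPKM. Of 44 ribosome biogenesis genes 37 rose and none fell, or 39 and 1 adjusted over the list alone (median 0.34, camera adjusted p = 4.34e-17, and adjusted p = 0.348 with an estimated correlation). Of 31 immediate early genes 19 rose and none fell, or 20 and 2 adjusted over the list alone (median 0.4, camera adjusted p = 7.71e-09, and adjusted p = 0.348 with an estimated correlation). Of 40 ATF4 targets 30 fell and 3 rose, or 32 and 3 adjusted over the list alone (median -0.48, camera adjusted p = 5.02e-10, and adjusted p = 0.377 with an estimated correlation). In total 2034 genes rose and 2177 fell, against 1281 and 3382 on the RPKM scale as deposited. The count was 1550 without TOB2 replicate 2 and 2277 and 1344 without FLAG replicate 1 or 2.

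The paralogs were then set against each other within the same fit. Apart from the transgenes, 21 genes were higher with TOB1 and 20 with TOB2. HSPA6 stood at 8.38 ± 0.13 RPKM with TOB1 and 105 ± 3.7 with TOB2, a fold of 12.1 (log2 difference TOB1 minus TOB2 of -3.6 ± 0.06, limma adjusted p = 1.17e-10). EGR1 stood at 2.18 ± 0.011 against 15.5 ± 1.7 RPKM (log2 difference -2.6 ± 0.09, limma adjusted p = 1.35e-07) and ARC at 1.04 ± 0.22 against 9.81 ± 0.33 RPKM. GDF15 was higher with TOB1, at 3.66 ± 0.36 against 0.964 ± 0.061 RPKM (log2 difference 1.49 ± 0.13, limma adjusted p = 0.000296), as were INHBE, an inhibin subunit, at 2.97 ± 0.28 against 0.707 ± 0.074 RPKM, and ACTA2, at 7.49 ± 0.14 against 3.51 ± 0.39 RPKM. Of 27 p53 targets 5 were higher with TOB1 and none lower, or 21 higher adjusted over the list alone (median log2 difference 0.26, camera adjusted p = 1.36e-27). The call held with an estimated correlation (camera adjusted p = 0.00139). The G2/M list (40 measured, median 0.1) was also higher with TOB1 with either correlation (camera adjusted p = 3.61e-10 and 0.00182), though no member passed over all genes or adjusted over the list alone. Of 31 immediate early genes 7 were lower with TOB1 and none higher, or 12 and 1 adjusted over the list alone (camera adjusted p = 4.16e-15, and adjusted p = 0.184 with an estimated correlation). Without TOB1 replicate 1 or 2 the count was 19 and 19, and without TOB2 replicate 1 or 2 it was 25 and 23.

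Overlaps between comparisons were read against the controls they shared. TOB1 and TOB2 shared 1410 higher and 1467 lower genes, where independent lists of those sizes would share 229.2 and 265.8, and 5 genes went opposite ways. The covariance of their log2 changes across genes was 0.0629, against 0.00877 in 20 simulations of unchanged groups that shared simulated controls, with a correlation of 0.75 against 0.5. In the 14 other pairs of overexpression groups the covariance lay between 0.0414 and 0.0646. In all 6 groups 385 genes were higher and 408 lower. The simulations gave 0 each way, but they held no shift of a whole library. They cannot tell what overlap shifted FLAG libraries would give. DDX6 and MEX3C knockdown shared 851 higher and 1694 lower genes (307.5 and 889 for independent lists, covariance 0.114 against a simulated 0.0123, correlation 0.64 against 0.67). AIMP1 and MEX3C knockdown went opposite ways in 2042 genes and shared 74 and 168, with a covariance of -0.056 against a simulated 0.0124. The hairpins of one target shared 1954 higher and 98 lower genes for AIMP1 (449.3 and 4 for independent lists), 1591 and 2783 for MEX3C (585.9 and 1550.6), 270 and 452 for DDX6 (67.5 and 138.9), 282 and 328 for CNOT7 with 174 opposite (110.4 and 154.6), 46 and 29 for UBAP2L (3.5 and 5.9), 2 and 1 for PARN and none for MTDH. The covariance between hairpins was 0.134 for AIMP1, 0.23 for MEX3C, 0.0745 for DDX6, 0.0239 for CNOT7 and 0.0229 for UBAP2L, against simulated values of 0.0125, 0.0123, 0.0122, 0.0136 and 0.0135. For PARN it was 0.0498 against 0.0357, and for MTDH 0.00564 against 0.0355, below the lowest draw of 0.0313. The correlation between hairpins lay above the simulated 0.5 for AIMP1 (0.92), MEX3C (0.67) and DDX6 (0.61) and below it for PARN (0.48), UBAP2L (0.37), CNOT7 (0.16) and MTDH (0.06). With 2 controls per table the controls could not be split, and part of each excess may come from the shared controls.

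**Figure D5:**
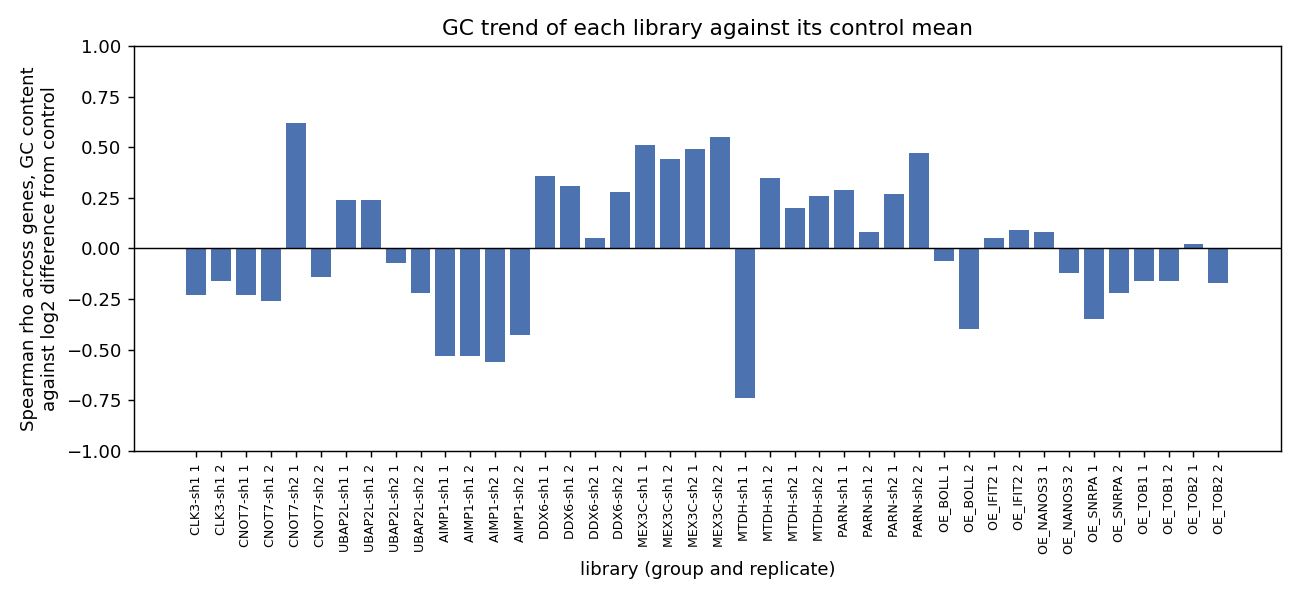
Spearman rho across genes between gene GC content and the log2 difference of each library from the mean of its controls (vertical axis, from -1 to 1), for each knockdown and overexpression library on the horizontal axis. The 4 AIMP1 libraries lie between -0.56 and -0.43, the 4 MEX3C libraries between 0.44 and 0.55, and MTDH-sh1 replicate 1 (-0.74) and CNOT7-sh2 replicate 1 (0.62) stand apart from their partners.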

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

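The comparison of hairpins was set with the design, and none of its tests was chosen after the result was seen. Hairpins of one target should leave similar levels of it, and in 2 of 7 targets the level differed, as a test of hairpin 1 minus hairpin 2 adjusted over the 7 targets showed. The log2 difference was 0.45 for UBAP2L (limma adjusted p = 0.00148) and 1.39 for PARN (limma adjusted p = 0.000162), hairpin 2 leaving less of each.

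The same contrast over all genes gave 6527 genes that differed between the hairpins for CNOT7, 1555 for UBAP2L, 2023 for DDX6, 6050 for MEX3C, 65 for MTDH and 203 for PARN, and none for AIMP1. On the RPKM scale as deposited the split was 1184 higher and 552 lower for UBAP2L, 434 and 2296 for DDX6, and 5837 and 1461 for MEX3C. Leaving out 1 library moved most of these counts, with ranges given below. Errors are pooled over a table, so the wide CNOT7-sh2 and MTDH-sh1 pairs (SD 0.495 and 0.833) enter the p-values of CLK3, UBAP2L and PARN too. With the compared groups alone the count was 60 for CNOT7 and 0 for MTDH, and without the expression filter 0 for MTDH. With the replicate block the counts were 0 for MTDH and PARN and 552 for UBAP2L. The cause of the differences was not tested.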

How the results depend on the processing

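The alternatives were set with the design except the adjustment for GC content and gene length, voom on recovered reads, the list tests without the targeted gene, and the fits without CNOT7-sh2 replicate 1 or MTDH-sh1 replicate 1, which were chosen after the result was seen. Over all alternatives 209 of 343 named gene results and 4 of 172 list results kept their call and direction, since 168 lists lost theirs with an estimated correlation. Counts moved over 1.5-fold in 120 of 303 fits, named genes weakened in 381 of 4603 fits and reversed in 3, and lists weakened in 333 of 2315 and reversed in 11. Without the targeted gene, the stress granule list of UBAP2L and the germ cell list of BOLL no longer passed (camera adjusted p = 0.201 and 0.129, against 0.0477 and 0.00738 with it). Fits without 1 library leave a lone library that is assumed to vary like the other groups.

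With 1 library left out, the count of changed genes ranged from 61 to 3585 for CLK3, 394 to 8032 for CNOT7, 1 to 3277 for UBAP2L, 1479 to 2930 for AIMP1, 728 to 4018 for DDX6, 6285 to 8397 for MEX3C, 0 to 7645 for MTDH, 0 to 4009 for PARN, 1533 to 3439 for BOLL, 51 to 907 for IFIT2, 1837 to 3854 for NANOS3, 1748 to 3518 for SNRPA, 1092 to 2051 for TOB1, 1344 to 2852 for TOB2 and 19 to 25 for TOB1 against TOB2.

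For the differences between hairpins the range was 3352 to 10577 for CNOT7, 169 to 5239 for UBAP2L, 0 in every fit for AIMP1, 538 to 2664 for DDX6, 4493 to 5772 for MEX3C, 0 to 11124 for MTDH and 0 to 4399 for PARN.

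With the compared groups alone in the fit the count was 2053 for CLK3, 61 for CNOT7, 3773 for UBAP2L, 2654 for PARN, 1400 for BOLL and 2808 for NANOS3, and for hairpin differences 60 for CNOT7, 5395 for UBAP2L, 3 for AIMP1, 1104 for DDX6, 0 for MTDH and 2623 for PARN. After adjustment for GC content and gene length it was 1861 for CLK3, 5031 for CNOT7, 1458 for UBAP2L, 198 for MTDH and 1084 for PARN, and for hairpin differences 2713 for UBAP2L, 1791 for MTDH and 2518 for PARN. MTDH itself then passed, at a log2 change of -1.58 (limma adjusted p = 0.0047). With hairpin 1 or 2 alone the count was 5015 and 1649 for CNOT7 and 500 and 585 for UBAP2L, with hairpin 1 alone 5312 for MEX3C, 1 for MTDH and 143 for PARN, and with hairpin 2 alone 1098 for DDX6. Without the expression filter it was 5169 for AIMP1, 4 for PARN and 0 for the hairpins of MTDH. PARN gave 2 with a pseudocount of 0.1, 27 on the RPKM scale as deposited and 28 with voom, and TOB1 against TOB2 gave 68 with voom.

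With 1 library left out, the log2 change of the targeted gene was -1.36 throughout for CLK3 and ranged from -3.03 to -2.84 for CNOT7, -1.41 to -1.31 for UBAP2L, -0.99 to -0.64 for AIMP1, -0.69 to -0.66 for DDX6, -0.49 to -0.42 for MEX3C, -1.74 to -1.34 for MTDH and -1.74 to -1.59 for PARN. PARN did not pass in 6 of these fits (limma adjusted p from 0.0984 to 0.411). It ranged from 9.37 to 9.6 for BOLL, 13.37 to 13.46 for IFIT2, 14.09 to 14.27 for NANOS3, 6.34 to 6.36 for SNRPA, 10.1 to 10.17 for TOB1 and 9.03 to 9.12 for TOB2.

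Directions reversed mostly between hairpins. With hairpin 2 of CNOT7 alone COL4A1 stood at 0.2 (limma adjusted p = 0.158), PFKP at 0.15 (0.363) and WARS1 at -0.01 (0.972), and the medians were -0.21 for ATF4 targets (camera adjusted p = 0.000295) and -0.14 for aminoacyl-tRNA synthetases (0.664). For UBAP2L the medians were -0.05 for ATF4 targets (camera adjusted p = 0.325) and 0.02 for hypoxia genes (0.768) with hairpin 1 and 0.09 for histones (0.787) with hairpin 2. With hairpin 2 the ribosomal proteins stood at -0.04 for DDX6 (camera adjusted p = 0.736) and ribosome biogenesis at -0.08 for MTDH (0.0686), and with hairpin 1 histones stood at -0.05 for MTDH (camera adjusted p = 0.615) and hypoxia genes at 0.03 for PARN (0.796). The SR proteins of AIMP1 stood at 0.17 after adjustment for GC content and gene length (camera adjusted p = 0.828), still above 0, and only the camera direction, which is relative to the other genes, turned. The hypoxia genes of BOLL stood at -0.04 without BOLL replicate 1 (camera adjusted p = 0.885) against up to 0.28 without FLAG replicate 1.

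The replicate numbers tied no libraries together, since correlations between groups by number lay between -0.44 and 0.34 over the 4 tables. As a replicate block they gave counts of 4448 for BOLL, 2412 for IFIT2, 5072 for NANOS3, 4916 for SNRPA, 3945 for TOB1 and 4373 for TOB2, and moved 3 hairpin counts, to 552 for UBAP2L, 0 for MTDH and 0 for PARN. Of 157 named genes 2 lost their call with the block, RN7SKP80 in SNRPA (limma adjusted p = 0.0529) and SLC7A11 in IFIT2 (limma adjusted p = 0.0505), and of 92 lists none did.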

Other observations

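Gene sets found in one table were carried to the others, with all 22 tests chosen after the knockdown results were seen. Of these 10 passed with the preset correlation and none with an estimated correlation. Genes that rose with CNOT7 knockdown (1136 of them tested) were higher with PARN knockdown, at a median log2 change of 0.18 (camera adjusted p = 4.17e-17, and adjusted p = 0.069 with an estimated correlation), and those that fell were lower (median -0.1, camera adjusted p = 1.95e-07, and adjusted p = 0.0683 with an estimated correlation). Genes that rose with UBAP2L knockdown were also higher with PARN knockdown (median 0.23, camera adjusted p = 1.93e-15, and adjusted p = 0.069 with an estimated correlation), and those that fell were lower (median -0.14, camera adjusted p = 8.29e-08, and adjusted p = 0.0683 with an estimated correlation). Others went against the direction in the first knockdown. Genes that rose with CNOT7 knockdown were lower with DDX6 knockdown (median -0.16 against -0.07 for all genes, camera adjusted p = 0.00119, and adjusted p = 0.155 with an estimated correlation), and genes that fell with UBAP2L knockdown were higher with AIMP1 knockdown (median 0.32 against 0.06, camera adjusted p = 0.00051, and adjusted p = 0.734 with an estimated correlation). The latter were lower with DDX6 (median -0.25, camera adjusted p = 0.00318, and adjusted p = 0.748 with an estimated correlation) and with MEX3C (median -0.66 against -0.23, camera adjusted p = 4.15e-10, and adjusted p = 0.595 with an estimated correlation). Genes that rose with CNOT7 knockdown were higher with TOB1 overexpression (median 0.05, camera adjusted p = 0.0116, and adjusted p = 0.595 with an estimated correlation), and genes that rose with DDX6 knockdown were higher with PARN knockdown (median 0.09, camera adjusted p = 0.0157, and adjusted p = 0.858 with an estimated correlation).

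The control libraries of the second table stood apart from the other controls, as values compared after the data were seen. Across genes the Spearman rho between GC content and the log2 difference of Control-2 from Control-1 was 0.76, and that of Control-3 and of FLAG from Control-2 was -0.78 and -0.74, against -0.04, 0.15 and 0.17 among the other 3 pairs of controls. AIMP1, whose GC content was 36.3 percent, was listed at 0.723 RPKM in Control-2 and at 16.6, 15.2 and 17.1 in the other controls, and DDX6 at 0.435 against 8.63, 7.95 and 6.88. The whole table differed, with 8732 to 11740 genes at RPKM of at least 1 per library, against 14270 to 15384 elsewhere. GC trends of its knockdown libraries against other tables were not tested. Levels of genes of low GC content in this table cannot be read against the others.

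Of the 14 tests of the 3 patterns below, those of GC content as the whole cause, of the covariance, of the differences among the 6 overexpression groups, of the targeted gene's level and of the share toward CNOT7-sh1 were chosen after the result was seen, and the others were chosen after the data were seen but before their result. Genes changed with AIMP1 and MEX3C knockdown along a gradient of GC content, in opposite directions. After adjustment for GC content and gene length 59.4 percent of 3034 called genes for AIMP1 and 60.6 percent of 8342 for MEX3C were still called in the same direction. The bias that the adjustment removed was therefore not the whole cause. Bias left behind by it could also keep such calls, so the test cannot exclude GC content bias as a whole. Control-2 libraries apart from every knockdown would, as the only cause, give a positive covariance between AIMP1 and MEX3C, and it was -0.056 (simulated 0.0124, lowest 0.012). That value restates the opposite directions and leaves a part played by the controls open. Such a bias, or a biological effect on transcripts of low GC content, may remain, and neither was separated from the other.

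Heat shock genes were higher and ATF4 targets lower than in the FLAG libraries in all 6 overexpression groups. If FLAG alone stood apart and the 6 were alike, no member would differ among them, yet 13 of 20 heat shock genes and 10 of 40 ATF4 targets did (limma F test). The lowest of the 6 heat shock medians was 0.43 after adjustment for GC content and gene length and 0.38 on the RPKM scale as deposited. A shift of the FLAG libraries common to all 6 comparisons, and a response to making any abundant protein, could each add to the pattern and were not separated.

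CNOT7-sh2 replicate 1 and MTDH-sh1 replicate 1 each stood apart from its partner. The SD of the log2 difference between partners fell from 0.495 to 0.317 for CNOT7 and from 0.833 to 0.574 for MTDH after adjustment for GC content and gene length, above every other pair of the table (at most 0.178 and 0.233). Among genes of at least 50 RPKM, where counting noise is small, it was 0.334 and 0.962 (at most 0.132 and 0.237 elsewhere). The targeted gene lay -0.14 of the way from partner to control for CNOT7 and 0.44 for MTDH, each below every library of its table without that knockdown. Among genes with GC content within 2 percentage points and a control level within 2-fold, 0 of 277 for CNOT7 (0 percent) and 9 of 684 for MTDH (1.3 percent) lay as far below the controls in the library, which argues against a sample without the knockdown in both. A mixture with such a sample was not tested. Over 429 genes at least 2-fold apart between CNOT7-sh1 and the partner, the library lay at a median of -0.05 of the way to CNOT7-sh1 (quartiles -0.29 and 0.21), which argues against a CNOT7-sh1 sample.

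Genes overexpressed elsewhere in the series were listed in some control libraries, as values noted after the data were seen. In the third table NANOS3 stood at 5.2 and 15.9 RPKM and IFIT2 at 2.19 and 0.11 in the Control-3 libraries, and in the second table NANOS3 stood between 0.805 and 2.63 RPKM in all 14 libraries. Levels per gene do not tell transgene from endogenous reads, and the source was not tested.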
